A study of Mus musculus with 2 samples.

How the data were processed

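Droplet-based 3' single-cell RNA sequencing was done on full-thickness back skin wounds of 10 mm from male C57BL/6 mice, per the labels. There was 1 library of pooled mice per age, 2 months and 24 months, both at day 6. The number of animals pooled and any separate preparation dates are not given in the sources used here. Wounds were digested with collagenase and dispase at 37 °C, red cells were lysed and libraries were sequenced on a NovaSeq instrument, per the labels' protocols. The labels name the kit both as version 3 and as version 3.1.

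The deposited values are raw UMI counts per gene and barcode, which the authors made with Cell Ranger 8.0.1, per the file headers. The submitters' processing notes name Cell Ranger 9.0, STAR, Seurat 4 and the GRCm38/mm10 genome, so the version differs between the sources. Of the features, 1684 had identifiers absent from the GENCODE M21 annotation of that genome. No coordinates are therefore given, and gene symbols are those in the deposited tables.

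The young library held 4932 barcodes and the aged library 4379. Cells with at least 500 UMIs, at least 200 detected genes and under 15% mitochondrial UMIs were kept. In the young library 212 barcodes had under 200 genes and 172 had 15% or more mitochondrial UMIs, and in the aged library 138 and 107. Scrublet scores, from scanpy with an expected 0.8% of doublets per 1000 cells, called 3 young and 2 aged doublets, or 0.0644% and 0.0475% of cells. A caller that marks so few cells has in effect not worked, so doublets have to be assumed to remain in the data. Whether any were removed before deposit is not known from the sources used here. Removing the top 4% of scores in each library was added as an alternative after seeing the data. The 4658 young and 4208 aged cells kept held 111168318 and 107472516 UMIs.

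Both libraries were clustered together in scanpy 1.11.5 with igraph 0.11.9 under Python 3.11.15. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, chosen within each library and leaving out the senescence, SASP, p53, proliferation and stress lists, 30 principal components and 15 neighbours were taken, with Leiden resolution 1. The interferon list was not left out of clustering. Of the 24 clusters, those with high levels of the genes of 1 of 17 fixed marker lists were given names ending in -like. Cluster 16 was left unnamed because its median UMI count was under 0.333 of its own libraries' medians with no neutrophil marker among its top 10 genes. Cluster 4 was left unnamed because its top 10 genes held Acta2, a marker of another list, and no fibroblast marker. The fibroblast-like clusters and the macrophage/monocyte-like cluster 5 also lacked a marker of their own list among their top 10 genes, but held no marker of another list there. Clusters 4 and 16 are compared by number. Clusters 9, 19 and 23 had no name.

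UMIs were summed per library over all cells and per class with at least 100 cells in each library (senescence genes in smaller classes too), and scaled to equal totals as CPM. CPM values carry exact Poisson intervals, shares exact Clopper-Pearson intervals, and aged/young ratios exact conditional binomial intervals, all at 95% and covering counting error only. A count of 0 was given a floor of 3 counts. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, which left out 236 young and 291 aged cells. In cells so thinned, SASP lists were compared between cells with and without a Cdkn1a UMI, in classes with at least 30 cells with such a UMI in each library.

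The 21 gene lists cover the senescence core, SASP chemokines, cytokines, proteases and growth factors, p53 targets, collagen and matrix, contractile genes, angiogenesis, proliferation, interferon response, MHC class II, alternative and inflammatory macrophage genes, efferocytosis and lipid handling, hypoxia and glycolysis, wound-edge keratinocytes, antioxidant genes, dissociation stress, erythroid genes and mitochondrial transcripts. For each list the median log2 aged/young CPM ratio, with 5 CPM added, was taken over members with at least 20 UMIs. Its counting interval came from 200 Poisson redraws, and its percentile from 10000 random lists matched on mean expression. The percentile describes these libraries only. A member was counted as higher or lower at a ratio of 1.5 or more in either direction. The lists share members, such as Cxcl10, Tnf, Ccl24 and Tgfb1.

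Genes were named by a fixed rule. In each class these are the 10 highest and 10 lowest log2 ratios among genes with at least 50 UMIs, an interval beyond 1.5-fold and a CPM of at least 20% of the highest class, leaving out mitochondrial, ribosomal, haemoglobin, immunoglobulin, sex-linked and unnamed genes. In each list described, these are the 2 highest and 2 lowest members. The text says where other genes were chosen after their values were seen, and Spp1 cells, MHC class II cells and T cell genes over all barcodes are among these. The sample groups, tests, gene lists, markers, naming rule for genes and most alternatives were fixed before the data were examined.

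The summed-count ratios were tested on simulated data with 200 genes of known fold. Intervals covered the true ratio for 95.7% of 15561 genes in fibroblast-like cells, 95.7% of 11693 in macrophage/monocyte-like cells and 95.5% of 6971 in neutrophil-like cells. In fibroblast-like cells the size rule recovered 85.1% of genes simulated at 2-fold and 66.7% of those at 0.5-fold. In neutrophil-like cells it recovered 68.3% and 28.9%, and in cluster 16 it recovered 42.3% and 25%.

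Alternatives were tried for the cell filter, doublets, clustering, scaling (TMM in edgeR 4.0.16 under R 4.3.3, and the mean of per-cell CPM), thinning, pseudocount and count minimum. TMM moved all genes by -0.11 log2 over all cells, -0.28 in macrophage/monocyte-like cells, -0.11 in neutrophil-like cells and -0.14 in cluster 4. Clusters of the other clusterings were named by the class most of their cells had in the main clustering. This naming was adopted after an earlier rule, the nearest marker profile, had been tried and its names and values seen, because that rule misnamed clusters. The nearest marker profile was still used for libraries clustered separately. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9.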

Results

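The series concerns how the senescence response of a healing skin wound differs with age. Single-cell RNA sequencing counted transcripts in cells from wounds made through the full thickness of the back skin of male C57BL/6 mice, an inbred strain, and taken at day 6. There were 2 libraries, 1 from young mice of 2 months and 1 from aged mice of 24 months, each from several animals pooled. The young library held 4932 barcodes with 111810068 unique molecular identifiers (UMIs), and the aged library 4379 barcodes with 107865898. After filtering, 4658 young and 4208 aged cells remained, with a median of 15562 and 13766 UMIs and 3245 and 3408 detected genes. With 1 library per age there was no replicate and no test between ages. All intervals are 95% intervals that cover counting error only, and every difference is between these 2 libraries, in which age, the pooled animals and the library preparation cannot be told apart.

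The first comparison was of the cells that made up the wound. Macrophage/monocyte-like cells were 21% of young and 32.1% of aged cells, 1.53-fold more in the aged library (1.41 to 1.66). Neutrophil-like cells were 26.2% of young and 12.5% of aged cells, a ratio of 0.477 (0.430 to 0.529). T/NK-like cells were 7.56% and 1.31%, or 352 and 55 cells, 5.78-fold fewer in the aged library (4.34 to 7.83). Dendritic cell-like cells, which carry antigen to T cells, were 0.902% and 2.47%, a ratio of 2.74 (1.90 to 4.02). Fibroblast-like cells, the makers of wound matrix, were 26.1% and 28.9%, a ratio of 1.11 (1.02 to 1.20). Endothelial-like cells were 1.46% and 1.33%, and that ratio of 0.912 had an interval from 0.628 to 1.32, so no difference was detectable. Lymphatic endothelial-like cells numbered 20 and 5 and adipocyte-like cells 25 and 1. Both share ratios were 0 with libraries clustered separately or without the cells with the top 4% of doublet scores. So few aged cells could hardly form a cluster when the aged library was clustered alone, so the 0 from separate clustering says little.

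Some clusters stayed outside the named classes. Cluster 16 held 3.35% of young and 11.2% of aged cells and expressed neutrophil genes at a median depth of 0.319 of its own library's. Counted with the neutrophil-like class, it brought the ratio to 0.800 (0.737 to 0.869). Cluster 4, rich in collagen transcripts, was led by Prss35, Crabp1 and the smooth muscle actin gene Acta2. It held 6.33% and 4.92%, a ratio of 0.777 that was 0.409 with called doublets kept and 0.275 with libraries clustered separately. Keeping called doublets adds only 3 young and 2 aged cells and repeats the clustering. The move to 0.409 is therefore one of clustering, not of doublets. Fibroblast-like cells and cluster 4 together were 32.4% and 33.8%. Another 6.16% and 5.25% of cells remained unnamed. Neutrophil-like cells had few UMIs, with medians of 5784 and 4125, and the unnamed clusters fewer, with 2385 and 1264, so the depth filter bears on their shares.

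**Figure D1:**
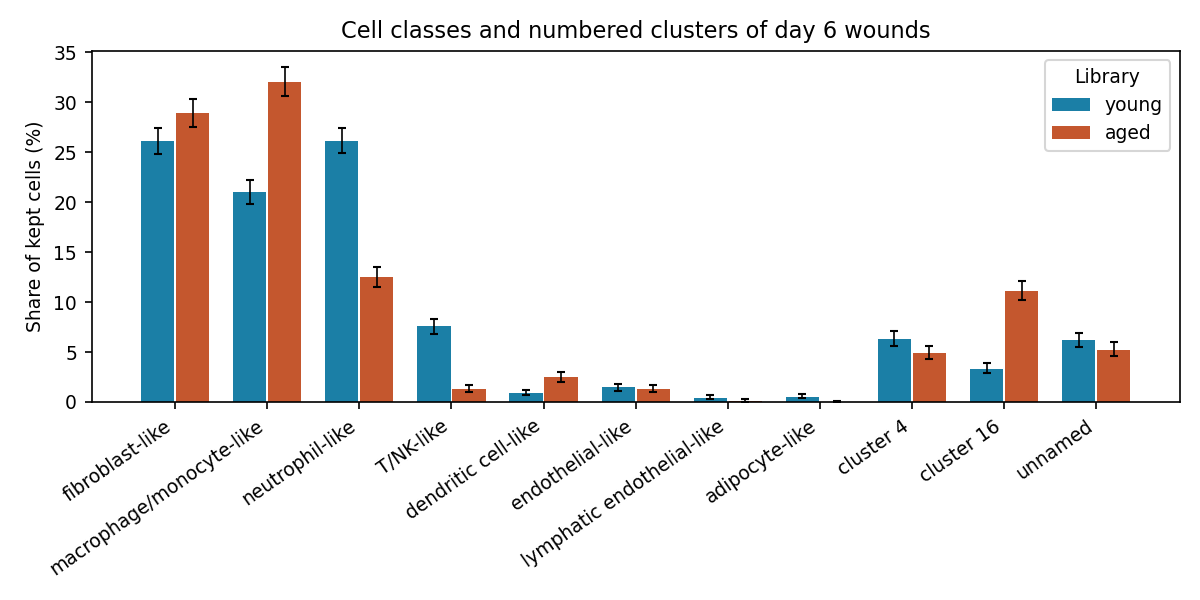
Share of kept cells (%) in each named class and numbered cluster, young (blue) and aged (orange) library. Bars are shares of 4658 and 4208 cells and lines exact 95% binomial intervals, and the macrophage/monocyte-like bar is taller in the aged library at 32.1% against 21%.

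The T/NK-like difference was marked by genes of interleukin 17-producing γδ T cells, chosen after their values were seen. Over all deposited barcodes, before the filter used here, Il17a, the gene of that cytokine, had 9773 UMIs in 303 young barcodes and 39 UMIs in 3 aged ones. Trdv4, a γδ receptor segment, had 4659 and 56 UMIs. Il23r, the receptor for interleukin 23, had 2042 and 75, Cxcr6, a chemokine receptor of tissue lymphocytes, 5733 and 113, and Cd3e, a part of the T cell receptor complex, 1824 and 79. Over the 10 detected T cell markers the median ratio was 0.160, and 8 of the 10 had an upper limit under 0.5. The exceptions were Thy1, which fibroblasts also express, at 1.16 and Cd8a at 2.54 on 11 and 27 UMIs. Of the T/NK-like cells, 213 young cells and 1 aged cell lay in cluster 14, led by Il17a and Trdc. A cluster held almost wholly by 1 library may be a feature of that library.

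The second comparison was of senescence genes. Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 activator p19Arf, was lower in the aged library. Its level over all cells was 11.5 CPM (UMIs scaled to equal library totals; 10.9 to 12.2) in the young and 4.72 CPM (4.32 to 5.15) in the aged library, a ratio of 0.410 (0.369 to 0.455). In fibroblast-like cells it was 18.9 CPM (17.8 to 20.1) and 4.46 CPM (3.96 to 5.01), a ratio of 0.236 (0.207 to 0.269). Cdkn1a, which encodes p21, the cell cycle inhibitor that p53 induces, was close in both libraries over all cells, at 580.1 CPM (576 to 585) and 552 CPM (548 to 557), a ratio of 0.952 (0.941 to 0.963). The mean of per-cell levels turned that Cdkn1a direction, with a ratio of 1.19. Counts at the 3' end cannot separate the p16 and p19Arf transcripts.

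Cdkn2a transcripts lay in few cells. Cluster 7, a fibroblast-like cluster led by Igfbp2, Coch and Grem1, held 637 of the 1056 young fibroblast-like UMIs, or 60.3%, and 32 of the 290 aged ones. Its own level was 174 CPM in the young and 20.02 CPM in the aged library. Without cluster 7 the fibroblast-like ratio was 0.507 and the ratio over all cells 0.750, and with cluster 4 counted in, the fibroblast-like ratio was 0.368. The ratio was under 1 in each of the other fibroblast-like clusters, from 0.416 to 0.653, with an interval that reached 1 in cluster 20 alone. In cluster 4, Cdkn2a was 10.8 and 16.6 CPM, a ratio of 1.53 (1.23 to 1.90). That ratio turned to 0.772 without the 10 cells with the most Cdkn2a UMIs in each library, since 10 of the 207 aged cells held 77.7% of the UMIs. Neutrophil-like cells had 0 Cdkn2a UMIs in both libraries.

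The share of cells with a Cdkn2a UMI was compared after thinning each cell to 2000 UMIs. Among fibroblast-like cells it was 3.22% (39 of 1213; 2.30 to 4.37) in the young and 0.743% (9 of 1212; 0.340 to 1.40) in the aged library, and 16.2% and 9.21% without thinning. As background, neutrophil-like cells had a Cdkn2a UMI in 0 of 1169 young and 0 of 484 aged cells. The floor of 3 counts stands at 0.257% and 0.620% there, and the exact upper limits are 0.315% and 0.759%. The median depth of neutrophil-like cells was 5784 and 4125 UMIs, against 42065 and 49752 in fibroblast-like cells. Among macrophage/monocyte-like cells the thinned count was 0 of 957 and 0 of 1289. The floors are 0.313% and 0.233% there, and the exact upper limits 0.385% and 0.286%. Without thinning, 6 of 978 young and 2 of 1349 aged cells of that class had a Cdkn2a UMI. Over all cells the Cdkn2a share was 1.18% and 0.332% thinned, and 6.48% and 4.06% unthinned. Its ratio over all cells was 0.282, and 0.428 with cells thinned to 1000 UMIs, and the fibroblast-like ratio of 0.231 was 0.1001 for cells with at least 2 UMIs.

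Cdkn1a differed by cell class. Fibroblast-like cells had 425 CPM (419.7 to 430.5) in the young and 342 CPM (337 to 346.5) in the aged library, a ratio of 0.804 (0.790 to 0.819). The thinned share of fibroblast-like cells with a Cdkn1a UMI was 39.3% (36.6 to 42.1) and 34.3% (31.7 to 37.1), and the unthinned share 89.6% and 86.0%. Macrophage/monocyte-like cells had 983 and 1113 CPM, a ratio of 1.13 (1.11 to 1.16) that turned to 0.931 with TMM scaling. Neutrophil-like cells had 1069 and 1211 CPM, a ratio of 1.13 (1.09 to 1.18). Endothelial-like cells had 779 and 894 CPM, a ratio of 1.15 (1.09 to 1.21), dendritic cell-like cells a ratio of 1.002 and cluster 4 a ratio of 0.999. Cluster 16 had 1724 and 1252 CPM, a ratio of 0.727 (0.681 to 0.775). Over all cells the thinned share was 58.0% and 60.8%.

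**Figure D2:**
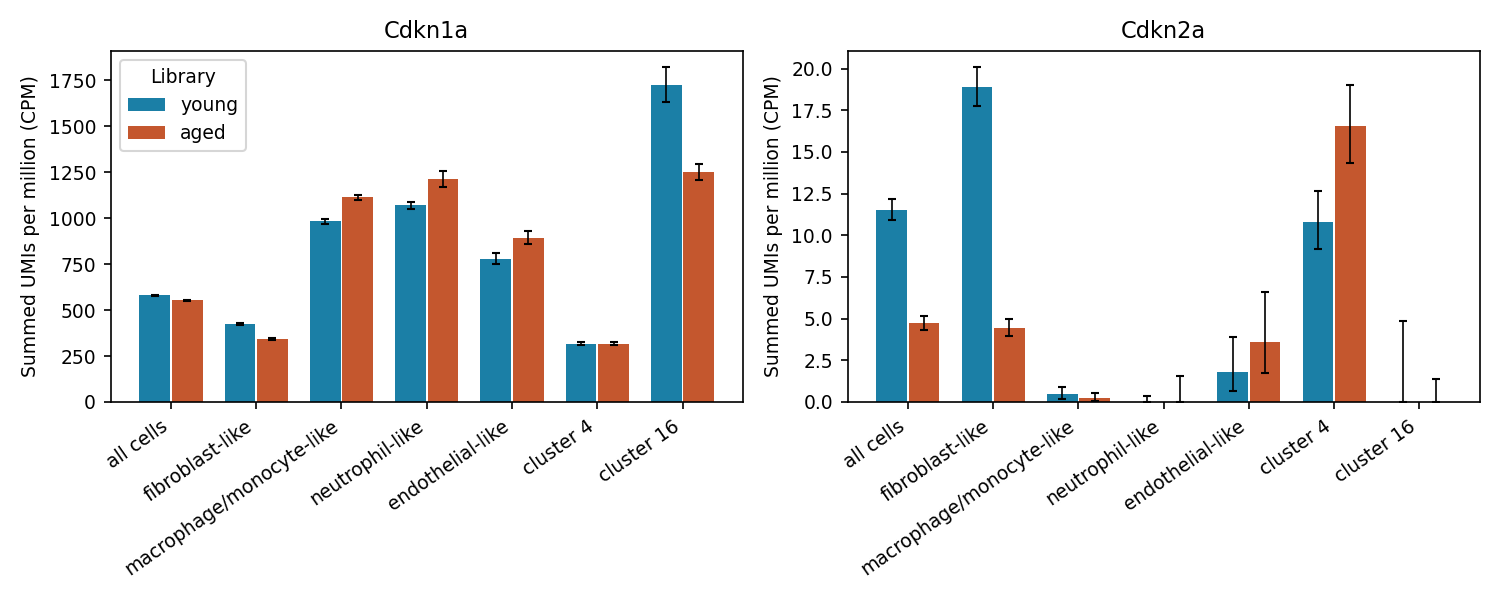
Summed UMIs scaled to equal library totals (CPM) of Cdkn1a (left) and Cdkn2a (right) in the young (blue) and aged (orange) library by cell class, with exact 95% Poisson intervals as lines. Cdkn2a in fibroblast-like cells stands at 18.9 CPM in the young and 4.46 CPM in the aged library.

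Cdkn1a and Cdkn2a belong to the senescence core list, which holds cell cycle inhibitors, p53 genes and other genes linked to senescence. It also holds Lmnb1, the lamin B1 gene that senescent cells typically lose, scored with the same sign. The list's median is therefore not a measure of more or less senescence. Over all cells the list's median log2 aged/young ratio was -0.10, at percentile 0.2 of 10000 matched random lists, and 3 of 16 members had a ratio under 1/1.5 and 0 had a ratio of 1.5 or more. Those 3 were Cdkn2a, Bcl2l1, the gene of the survival protein Bcl-xL, at 0.510 (0.488 to 0.533), and Trp53inp1, which p53 induces, at 0.521 (0.4845 to 0.560). By class, Bcl2l1 had a ratio of 0.652 in neutrophil-like cells, which held 3598 of its 5977 young UMIs, 0.631 in fibroblast-like and 1.25 (1.15 to 1.36) in macrophage/monocyte-like cells. Trp53inp1 had 0.412 in T/NK-like, 0.721 in fibroblast-like and 1.78 (1.30 to 2.45) in macrophage/monocyte-like cells. Glb1, which encodes the lysosomal β-galactosidase, was highest over all cells at 1.17 (1.11 to 1.24), with 1.07 in fibroblast-like and 1.45 in macrophage/monocyte-like cells. In fibroblast-like cells the median was -0.13, but 0.11 (0.05 to 0.18) within cluster 3 and 0.02 (-0.06 to 0.08) within cluster 8, which together hold most of the class. Over the class, Lmnb1 was 1.32-fold higher (1.24 to 1.41) in the aged library, while over all cells its ratio was 0.867 (0.846 to 0.8885). The p53 target list had a median of -0.13 in fibroblast-like cells, where 3 of 22 members were lower by that measure, among them Bbc3, a cell death gene, at 0.518 and Ddit4, a stress-induced brake on mTOR, at 0.630. In macrophage/monocyte-like cells the core median of 0.15 and the p53 target median of 0.12 turned to -0.12 and -0.10 with TMM scaling, and in cluster 4 the core median of 0.03 turned to -0.07. In cluster 16 the core median was -0.56, with 7 of 13 members lower, and the p53 target median was -0.46. The dissociation stress and mitochondrial medians of cluster 16 were lower too, at -0.42 and -0.48, and so were those of fibroblast-like cells, at -0.41 and -0.26.

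Genes of the senescence-associated secretory phenotype (SASP), factors that senescent cells secrete, differed by class. The lists were summed over all cells of a class, so they do not measure the output of senescent cells. They share Ccl3, Ccl4, Cxcl10, Il1b, Il6 and Tnf with the inflammatory macrophage list. In macrophage/monocyte-like cells the SASP chemokine list had a median log2 ratio of -0.78, with 9 of 15 members lower and 3 of 15 higher by 1.5-fold or more. Within clusters 5, 11 and 17 that median was -0.33, -0.21 and -0.39, and within cluster 13 -1.22. Ccl5, which draws T cells, had a ratio of 0.150 and Cxcl10 0.418, while Ccl24, which draws eosinophils, was 4.12-fold higher. Their SASP protease list had a median of -0.24, led by Mmp8, the neutrophil collagenase, at 0.215, and their SASP cytokine list a median of -0.20, led by Csf3, the granulocyte growth factor, at 0.305. Their SASP growth factor list had a median of 0.09, which turned to -0.04 with TMM scaling, with Bmp2 at 3.15 and Inhba, the activin A subunit, at 0.283. In fibroblast-like cells the SASP chemokine, cytokine, protease and growth factor medians were 0.12, 0.02, -0.11 and 0.04. There Spp1, the gene of osteopontin, was 4.87-fold higher in the aged library (4.73 to 5.01), with 10 cells holding 49.0% of its aged UMIs, and Mmp3, stromelysin, had a ratio of 0.434. In neutrophil-like cells the chemokine median was -0.38 and Ccl2, a monocyte attractant, had a ratio of 0.267. In cluster 16 the cytokine median was 0.71, and 8 of 14 members were higher.

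Cells with a Cdkn1a UMI were set against cells without one, to see whether SASP genes went with Cdkn1a. In macrophage/monocyte-like cells all SASP lists together stood at 90324 CPM in cells with and 73871 CPM in cells without a Cdkn1a UMI in the young library, a ratio of 1.22 (1.21 to 1.24), and at 56936 and 43668 CPM in the aged library, a ratio of 1.30 (1.28 to 1.32). With cells thinned to 1000 UMIs these ratios were 1.015 (1.001 to 1.029) and 1.21 (1.19 to 1.23), and the protease list alone went the other way in the young library, with 0.904 (0.870 to 0.939) at 2000 UMIs. In fibroblast-like cells the ratios were 0.970 (0.958 to 0.981) and 0.982 (0.970 to 0.994), and the young one turned to 1.02 with cells thinned to 1000 UMIs. Their lists went apart, with the chemokine list at 0.924 and 0.958 but the cytokine list at 1.07 (1.02 to 1.12) and 1.11 (1.06 to 1.16) and the growth factor list at 1.15 (1.11 to 1.19) and 1.05 (1.01 to 1.08). With cells thinned to 1000 UMIs the aged cytokine ratio was 0.988 (0.921 to 1.06) and the aged growth factor ratio 1.01 (0.954 to 1.07). The young ones were then 1.21 and 1.12, and the chemokine ratios 0.987 (0.962 to 1.01) and 0.940. At 2000 UMIs, the ratios of all SASP lists together were 0.994 and 0.920 in neutrophil-like cells, 1.08 and 0.861 in cluster 4, and 1.03 and 0.922 in cluster 16. Dendritic cell-like cells had ratios of 3.13 (2.56 to 3.86) and 2.11 (1.92 to 2.32), resting on 6 and 21 cells without a Cdkn1a UMI. Endothelial-like cells had 1.71 (1.56 to 1.86) and 0.864 (0.788 to 0.947), with 16 and 14 such cells.

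The third comparison was of expression within each class. Summed over the class, fibroblast-like cells of the aged library had higher levels of interferon-induced genes. The interferon response list had a median log2 ratio of 0.99 (0.92 to 1.04), at percentile 100 of the random lists, and 17 of 21 members had a ratio of 1.5 or more. Ifit1, an antiviral RNA-binding protein, was at 62.2 and 341 CPM, 5.48-fold higher (5.29 to 5.68), and Cxcl9, a chemokine for activated T cells, at 79.0 and 333 CPM, 4.21-fold higher (4.08 to 4.36). Ifit3, Rsad2, Cxcl10 and the interferon-induced GTPase gene Irgm1 were 4.07-fold, 3.52-fold, 2.88-fold and 3.22-fold higher. Without thinning, Ifit1 UMIs were found in 613 of 1216 aged and 344 of 1216 young fibroblast-like cells, whose median depth was 49752 and 42065 UMIs. Clusters 3 and 8 held most of the class in both libraries, and the median was 1.18 within cluster 3 and 1.39 within cluster 8, which Ifit1 helped to define. The smaller clusters of the class, looked at after these values were seen, went apart, with 0.67 (0.50 to 0.75) in cluster 1 and 0.56 (0.47 to 0.76) in cluster 20, but -0.04 (-0.19 to 0.05) in cluster 10 and -0.51 (-0.69 to -0.25) in cluster 7. In cluster 4, the collagen-rich cells outside the class, the interferon median was 0.04 (-0.01 to 0.13), with 4 of 20 members higher and 2 lower by 1.5-fold or more.

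Over the same class, the aged library also carried more cell cycle transcripts. The proliferation list had a median of 0.43 (0.38 within cluster 3 and 0.09 within cluster 8). Of its 24 members, 16 had a ratio of 1.5 or more, among them Plk1 at 2.53 and Cdk1 at 2.10, kinases of cell division. Cluster 1, with Top2a, Ube2c and histone genes among its leading genes, held 88 of 1216 young and 148 of 1216 aged cells of the class. How much of the list's median came from it was not tested. Ttn, with a ratio of 0.147 over the class, also led that cluster. The thinned share of cells with a UMI of Mki67, a gene of dividing cells, was 3.55% (2.58 to 4.75) and 7.51% (6.09 to 9.14), and 14.2% and 23.8% without thinning. The thinned share in neutrophil-like cells, which do not divide, was 1.71% and 3.31%. The contractile list had a median of 0.20, with Acta2 at 2.04 (1.95 to 2.13) and Tpm2, a tropomyosin, at 1.76. Its median was 0.27 in cluster 4, which Acta2 helped to lead and which lay outside the class. Over all cells it was 0.04 and turned to -0.06 with TMM scaling. The collagen and matrix list had a median of -0.06, with Eln, the elastin gene and a leading gene of cluster 3, at 0.431 and Fbn1, fibrillin 1, at 1.39.

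Ctla2a, which encodes a cathepsin inhibitor, had the lowest log2 ratio with 5 CPM added in aged fibroblast-like cells, at 664 CPM (657 to 671) in the young and 52.8 CPM (51.1 to 54.6) in the aged library, 12.6-fold lower (12.1 to 13.02), with a UMI in 752 and 373 of 1216 cells. Akr1c18, a progesterone-metabolising enzyme, Tmem67, a protein of the ciliary transition zone, and the serpin gene Serpinb10 were 3.59-fold, 3.57-fold and 2.92-fold higher. Of their aged UMIs in the class, 91.4% for Akr1c18 lay in cluster 8, and 76.1% for Tmem67 and 57.7% for Serpinb10 in cluster 10, clusters that these genes helped to define. The other 10 genes picked by size had 50% or more of their UMIs in 10 cells. Of these Sult1e1, oestrogen sulfotransferase, was 26.8-fold higher, and Igfbp2, Coch, Reg1, Prl2c2, Prl2c3, Sprr2d, Sprr2e, Ttn and Adgrl3 were lower, Igfbp2 by 21.5-fold and Coch by 38.2-fold. Of their young UMIs in the class, 96.7% for Igfbp2 and 99.2% for Coch lay in cluster 7, and 98.0% for Reg1 in cluster 3. These genes helped to define those clusters, so the sizes of clusters 3, 7, 8 and 10 are not compared between libraries. Without the 10 cells with the most UMIs, Ttn and Adgrl3 turned to ratios of 2.41 and 1.41. Prl2c2 and Prl2c3, like Sprr2d and Sprr2e, belong to families of near-identical copies, so their counts are uncertain.

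**Figure D3:**
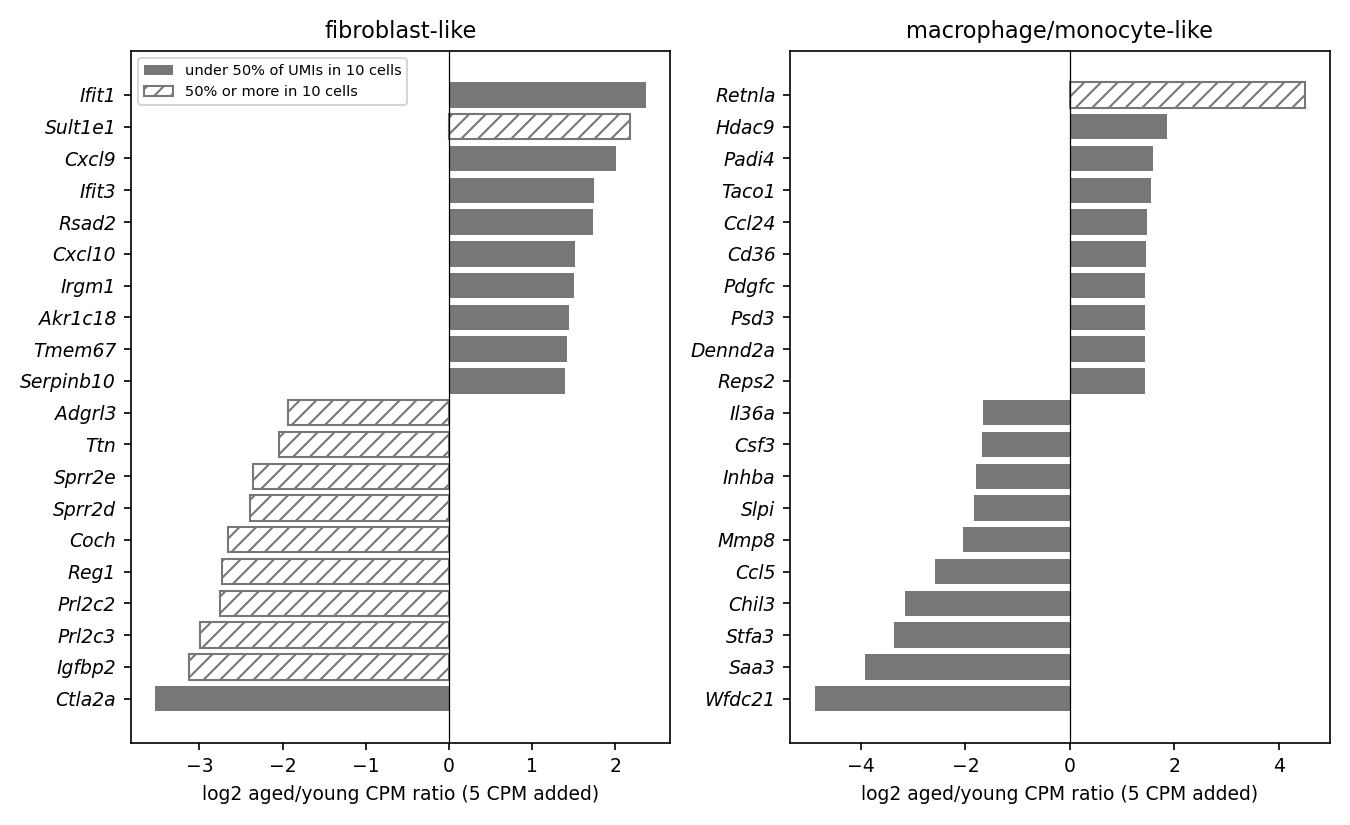
log2 aged/young CPM ratio, with 5 CPM added, of the 20 genes picked by size in fibroblast-like (left) and macrophage/monocyte-like (right) cells. Hatched bars mark genes with 50% or more of their UMIs in 10 cells of the higher library, which are 10 of 20 on the left and 1 of 20, Retnla, on the right.

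In fibroblast-like cells S100a8, a neutrophil gene, was at 73.6 CPM in the young and 19.4 CPM in the aged library, against 32399 and 18341 CPM in neutrophil-like cells, and Tnf, an inflammatory cytokine gene, at 11.7 and 2.03 CPM, against 2741 and 1540 CPM. The efferocytosis and lipid list had a median of -0.34, with Apoe, a lipid carrier, at 0.355, the inflammatory macrophage list -0.01, the alternative macrophage list 0.07, the angiogenesis list -0.03, the hypoxia and glycolysis list 0.14 and the antioxidant list 0.14. The wound-edge keratinocyte list, read over all cells, had a median of -0.18, with 6 of 14 members lower. That list holds S100a8 and S100a9, and neutrophil-like cells were 26.2% of young and 12.5% of aged cells. How far its median follows such cell shares was not tested. The dissociation stress list, genes induced by enzymes and warmth, had a median of -0.41 in fibroblast-like cells, with 8 of 19 members lower, Hspa1b at 0.296 among them. The erythroid list had a median of -1.76 there (-3.46 with 1 CPM and -0.70 with 20 CPM added), and mitochondrial transcripts -0.26. Haemoglobin transcripts were 0.0696% of UMIs in young and 0.00867% in aged cells.

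Macrophage/monocyte-like cells of the aged library had lower inflammatory genes and higher genes of the alternative, repair-type state. The inflammatory list had a median of -0.86 (-0.89 to -0.82), with 11 of 14 members lower by 1.5-fold or more, and the alternative list a median of 0.57 (0.53 to 0.60), with 8 of 16 higher. TMM scaling shifted all genes of this class by -0.28 log2, and the medians became -1.11 and 0.29. Within clusters 5, 11, 13 and 17 the inflammatory median was -0.26, -0.59, -1.12 and -0.56, and the alternative median -0.00, 0.43, 0.69 and 0.48. Cd36, a scavenger receptor for lipids and dying cells, was at 326 and 904 CPM, 2.77-fold higher (2.69 to 2.86), and Ccl24 4.12-fold higher (3.37 to 5.07). Pdgfc, a growth factor gene, was 2.91-fold higher, Hdac9, a histone deacetylase, 3.91-fold, and Padi4, an arginine deiminase, 4.46-fold, along with Taco1, Psd3, Dennd2a and Reps2 at 2.83-fold to 3.60-fold. Retnla, a marker of interleukin 4 signalling, had 10 young and 2330 aged UMIs, but 58 of 1349 aged cells held them and 10 cells held 77.2%. Clusters 11 and 5 held most young and clusters 11 and 17 most aged cells of this class.

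Among the genes picked by size as lower in aged macrophage/monocyte-like cells, Saa3, serum amyloid A3, was at 7540 CPM (7500 to 7581) in the young and 495 CPM (485 to 505) in the aged library, 15.2-fold lower (14.9 to 15.5). Wfdc21, a secreted protease inhibitor family member, was 36.9-fold lower, Stfa3, a stefin, 12.9-fold, Chil3, the chitinase-like protein Ym1, 9.51-fold and Ccl5 6.67-fold. Mmp8, Slpi, a leukocyte protease inhibitor, Inhba, Csf3 and the cytokine gene Il36a were 3.28-fold to 4.76-fold lower. For each of these genes except Chil3 and Ccl5, cluster 5 held the largest part of the young UMIs of the class. That part ran from 39.5% for Saa3 to 95.6% for Il36a, and Stfa3 helped to define the cluster. How far the mix of clusters accounts for these folds was not tested. Chil3 belongs to the alternative list and went against its median. The interferon list had a median of -0.41 (-0.51 to -0.27), with 9 of 21 members lower and 2 higher, Ifit1 at 0.358 and Cxcl9 at 0.402. The medians of its clusters lay apart, at -0.49 in cluster 11 and -0.24 in cluster 13, but 0.47 in cluster 5 and 0.37 in cluster 17. The collagen list had a median of 0.36, which turned to -0.02 without the cells with the top 4% of doublet scores.

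In macrophage/monocyte-like cells the proliferation median was 0.13, contractile 0.01, angiogenesis 0.03, MHC class II -0.13, hypoxia -0.10, keratinocyte -0.14 and mitochondrial -0.22. Those of efferocytosis (0.17), antioxidant (0.10) and dissociation stress (0.03) turned to -0.10, -0.18 and -0.25 with TMM scaling. The erythroid median was 1.12 (1.83 with 1 CPM and 0.45 with 20 CPM added), opposite to that in fibroblast-like cells.

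**Figure D4:**
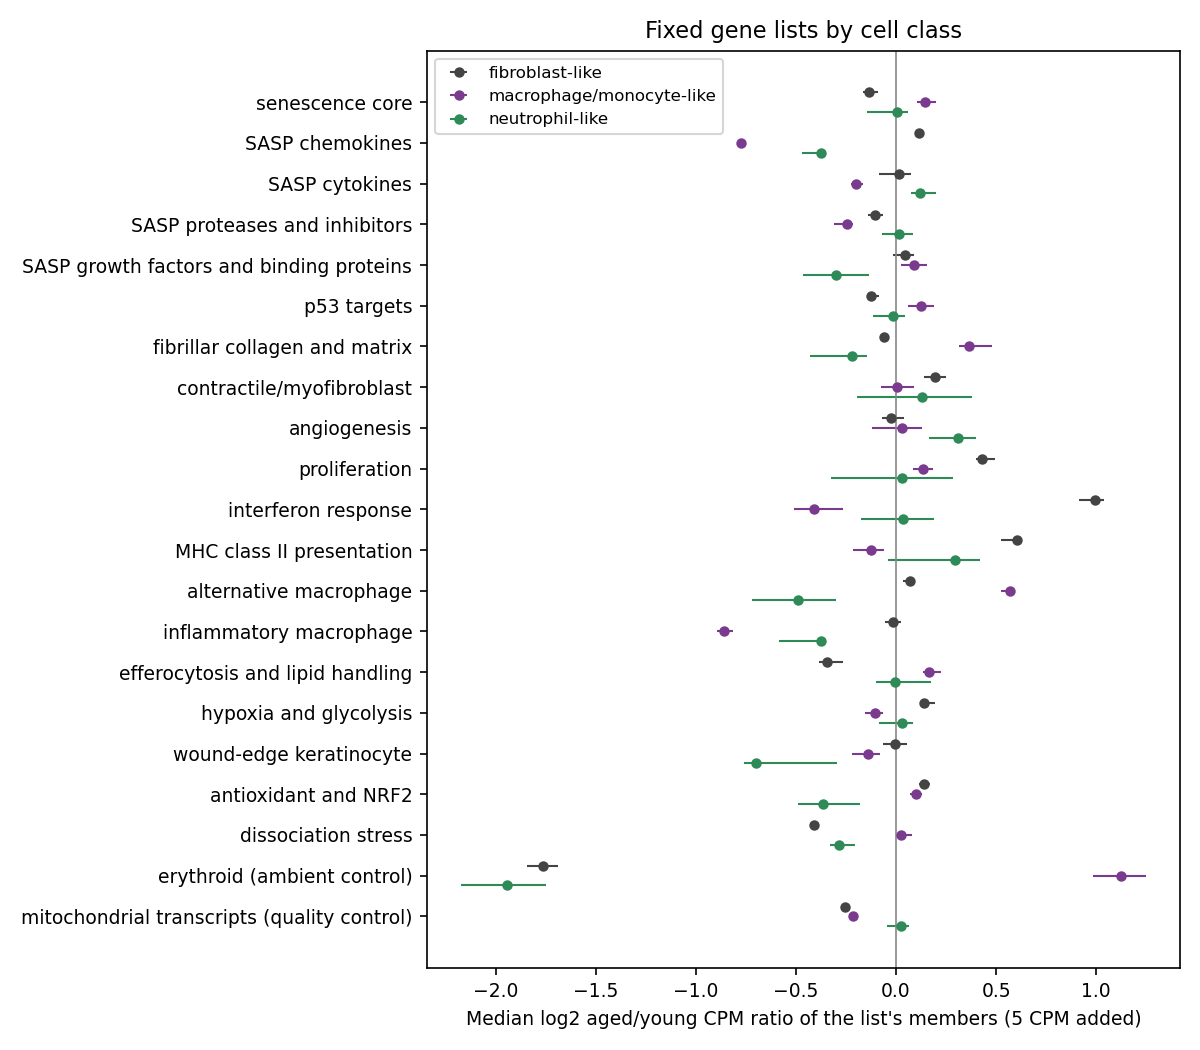
Median log2 aged/young CPM ratio of each gene list, with 5 CPM added, in fibroblast-like (grey), macrophage/monocyte-like (purple) and neutrophil-like (green) cells, with lines for the 95% counting interval. The interferon response list stands at 0.99 in fibroblast-like and -0.41 in macrophage/monocyte-like cells.

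Neutrophil-like cells of the aged library had more Thbs1, the gene of thrombospondin 1, at 1321 CPM (1299 to 1344) and 6222 CPM (6123 to 6323), 4.71-fold higher (4.60 to 4.82). Nt5e, an enzyme that makes adenosine, was 4.61-fold higher and the survival gene Bcl2a1a, which has near-identical copies and an uncertain count, 3.40-fold. Cmss1 was 2.93-fold higher, and Cldn1, Adgrv1, Gabbr1 and Abcc5 3.81-fold to 6.18-fold on at most 256 UMIs per library, with 10 cells holding 67.0% of the aged UMIs of Cldn1 and 57.6% of those of Abcc5. Mki67 and Tango6 were 4.92-fold and 4.64-fold higher, and 1.69-fold and 1.59-fold without the 10 cells with the most UMIs. Lower in the aged library were Chil3, with 3607 and 7 UMIs and a fold of 126 (61.3 to 315), Wfdc17 by 8.12-fold, Saa3 by 7.27-fold and Nos2, the inducible nitric oxide synthase gene, by 5.58-fold. Mmp8, Prnp, Klhl6, Ifitm1, Lipg and Wfdc21 were 4.07-fold to 9.41-fold lower. The class lay mostly in clusters 6 and 0 in the young and in clusters 6 and 12 in the aged library, and cluster 12 held 44.7% of the aged Thbs1 UMIs. Cluster 0 held 53.3% to 83.3% of the young UMIs of the 10 lower genes. The inflammatory list had a median of -0.37, alternative macrophage -0.49 (-2.05 over members with at least 100 UMIs) and dissociation stress -0.29, while the interferon median was 0.03.

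Cluster 16 shared several of these differences. Thbs1 was 4.61-fold higher in the aged library (4.28 to 4.96), and Chil3, Saa3, Wfdc17, Nos2 and Ifitm1 were 35.6-fold, 18.1-fold, 13.7-fold, 6.80-fold and 6.33-fold lower. Il23a, a subunit of interleukin 23, was at 96.7 CPM (75.8 to 121) and 858 CPM (823 to 894), 8.88-fold higher (7.03 to 11.4), and Bcl2a1a, Bcl2a1b and Bcl2a1d, copies that share reads, were 4.63-fold to 7.81-fold higher. Il23a was also the first leading gene of the neutrophil-like cluster 6, so its level in cluster 16 may depend on how the clustering parted the 2 clusters. Rhoh and Fchsd2 were 5.41-fold and 6.31-fold higher in cluster 16. Vmn2r96 had 0 young and 85 aged UMIs in 4 cells. H1f4, a histone gene, and Wfdc21 were 9.45-fold and 6.52-fold lower. In cluster 16, 10 cells held 79.2% and 79.4% of the young UMIs of Chil3 and Saa3, and Kdm4d, Ckap2l, Dmkn, Lipg and Stfa2 likewise had 50% or more of their UMIs in 10 cells. The interferon median was -0.73 and turned to 0.05 over members with at least 100 UMIs.

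Cluster 4 showed Ctla2a at 538 CPM (526 to 550) in the young and 15.04 CPM (12.9 to 17.4) in the aged library, 35.7-fold lower (30.8 to 41.7). Serpina3n, a protease inhibitor, Cp, ceruloplasmin, and Cryab, a small heat shock protein, were 5.76-fold, 3.78-fold and 3.57-fold lower, and Draxin and the olfactory receptor gene Or5m3b 5.60-fold and 9.55-fold. Pappa, a protease that frees insulin-like growth factors, was 2.66-fold higher (2.47 to 2.87), Tafa2 3.67-fold, Igsf9b 5.96-fold, Taco1 3.47-fold and Cdca3, a cell division gene, 3.65-fold. Tafa2 helped to define the cluster. The share ratio of cluster 4 moved with the clustering, and its gene ratios were taken in the main clustering only. Another 9 genes rested on 10 cells for 50% or more of their UMIs, namely Tac1, Tslp, Kcnq5, Ccl20 and Sprr2g, higher in the aged library, and Igfbp2, Epgn, Hpgd and Adgrb3, lower. Of these, Tslp, an epithelial cytokine, was 3.66-fold higher, Igfbp2 27.4-fold lower, and Sprr2g had 0 young and 96 aged UMIs in 1 cell. The proliferation list had a median of 0.54, with 15 of 24 members higher, the hypoxia and glycolysis list 0.44 and the dissociation stress list -0.57.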

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

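The tests of the patterns weighed here were set after the results were seen, although thinning and TMM scaling were themselves planned. With 1 library per age, age, the pooled animals and the library preparation cannot be told apart in any of them.

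Cdkn2a was lower in aged fibroblast-like cells, with a ratio of 0.236. A difference confined to cluster 7, in its number of cells or its level, is not the whole cause, since the ratio without that cluster was 0.507 (0.433 to 0.594), although the distance from 1 was then smaller. A few cells rich in Cdkn2a do not account for it either, with a ratio of 0.212 (0.179 to 0.251) without the 10 cells with the most UMIs in each library. Different depth would raise the aged share of cells with a UMI, since aged cells were deeper, at a median of 49752 against 42065 UMIs. That share was lower all the same, with a ratio of 0.569 without thinning and 0.231 (0.0984 to 0.485) with it. Thinning could hardly have come out otherwise, and the CPM ratio is already scaled to total UMIs. A lower Cdkn2a level in fibroblasts of aged wounds may remain as a hypothesis, with the pooled animals and the preparation untested.

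The T/NK-like share was 5.78-fold lower in the aged library. Loss of T cells in the filter or clustering used here is argued against as the whole cause. Over all deposited barcodes, before that filter, the median ratio of the 10 T cell markers was 0.160 (0.144 to 0.175). The smallest deposited barcodes held 501 young and 500 aged UMIs, so a loss before deposit cannot be tested. A stricter limit on each single marker was dropped after the result was seen, because Thy1, at 1.16, has 8018 of its 11692 young UMIs in fibroblast-like cells and Cd8a, at 2.54, rests on 11 and 27 UMIs. More unwounded margin skin in the young library was tested on 5 resident types, with a median share ratio of 0.277, of which adipocyte (0.0443), lymphatic (0.277), pericyte (0.158) and keratinocyte clusters (0.709; 0.521 to 0.959) had intervals under 1, but endothelial cells (0.912; 0.628 to 1.32) did not. Margin skin and an age difference cannot be told apart, since the resident types disagree and several number few cells.

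Interferon response genes went opposite ways, with a median log2 ratio of 0.99 in fibroblast-like and -0.41 in macrophage/monocyte-like cells, a difference that was not tested. In fibroblast-like cells another mix of clusters is argued against, since the median was 1.10 (1.03 to 1.15) with aged clusters weighted to young shares. In macrophage/monocyte-like cells it is argued against as the whole cause too, with a weighted median of -0.38 (-0.53 to -0.30), and a further limit, that no cluster lie above 0, was dropped after the result was seen because 0.47 in cluster 5, 0.37 in cluster 17 and -0.49 in cluster 11 are differences within clusters. Scaling to total UMIs could not be tested there with TMM. TMM moves all genes of this class by -0.28 log2, so the median could only fall further, to -0.64. An interferon response that differs with age may be a hypothesis for fibroblast-like clusters 1, 3, 8 and 20, not for cluster 10 at -0.04, cluster 7 at -0.51 or cluster 4 at 0.04, and for macrophages only in a direction that varies by cluster, both open to the pooled animals and preparation.

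Other results stood out because they went opposite ways in 2 classes, and none of these differences was tested. The SASP chemokine median was 0.12 in fibroblast-like and -0.78 in macrophage/monocyte-like cells. The collagen and matrix median was -0.0618 and 0.36 in the same order, but the second was -0.0215 without the cells with the top 4% of doublet scores. The MHC class II median was 0.60 and -0.13. The hypoxia and glycolysis median was 0.14 and -0.10. The erythroid median was -1.76 and 1.12. Cdkn2a had a ratio of 0.236 in fibroblast-like cells and 1.53 in cluster 4, where it was 0.772 without the 10 cells with the most UMIs.

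Signals outside the named classes also stood out. Cluster 9, with haemoglobin, Igkc, Rgs5 and Krt14 among its leading genes and a median of 1472 UMIs, held 200 young and 179 aged cells. Cluster 19, led by Igkc and Mcpt4 with a median of 835 UMIs, held 47 and 30. Cluster 23, led by Acp5, Atp6v0d2 and Mmp9, held 40 and 12.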

How the results depend on the processing

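Alternatives that count clusters 4 or 16 into a class, leave out cluster 7 or the 10 cells with the most UMIs of a gene, or remove the top 4% of doublet scores were chosen after seeing the data, and the others beforehand. Among those chosen beforehand, 48 of 59 class shares, 38 of 60 senescence gene ratios, 8 of 12 UMI shares, 0 of 10 SASP ratios, 76 of 108 named gene values and 565 of 739 list medians stayed within their counting intervals, and 0, 3, 0, 1, 0 and 15 reversed. Among those chosen after seeing the data, 11 of 14 class shares, 11 of 18 senescence gene ratios, 18 of 89 named gene values and 102 of 124 list medians stayed within them, and 0, 1, 2 and 2 reversed. For senescence genes and list medians, keeping called doublets left the classes as they were and added at most 3 young and 2 aged cells. Those values could hardly leave their counting intervals, so they weigh little in the tallies of alternatives chosen beforehand. Cdkn2a rests on 1056 and 290 UMIs in fibroblast-like cells. Libraries clustered separately gave no dendritic cell-like value, and SASP at 1000 UMIs none for dendritic cell-like or endothelial-like cells. No paired analysis was possible because each age has 1 library. For all values below the cause was not tested.

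For class shares, keeping called doublets adds only 3 young and 2 aged cells and repeats the clustering. With called doublets kept, share ratios were 1.23 for fibroblast-like, 0.624 for neutrophil-like cells, 0.409 for cluster 4 and 2.34 for cluster 16. With libraries clustered separately they were 1.28, 0.577 and, for cluster 4, 0.275, and 0 for lymphatic endothelial-like and adipocyte-like cells, which were also 0 with the top 4% of doublet scores removed. The neutrophil-like ratio was 0.565 with at least 500 genes, 0.618 under 10% mitochondrial UMIs and 0.800 with cluster 16 counted in.

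With TMM scaling Cdkn1a had ratios of 0.881 over all cells, 0.764 in fibroblast-like, 0.931 (reversed) in macrophage/monocyte-like and 1.05 in neutrophil-like cells and 0.909 in cluster 4. As the mean of per-cell CPM it was 1.19 (reversed), 0.861 and 1.16 in the first 3 of these and 1.05 in cluster 4, Cdkn2a was 0.293 over all and 0.189 in fibroblast-like cells, and Trp53 over all cells was 0.938 (reversed). With aged classes weighted to young shares, Cdkn1a and Cdkn2a were 0.875 and 0.466 over all cells. With cluster 4 counted in, they were 0.839 and 0.368 in fibroblast-like cells. Without cluster 7, Cdkn2a was 0.750 over all and 0.507 in fibroblast-like cells. Without the 10 top cells it was 0.350 over all cells and 0.772 (reversed) in cluster 4, and Ttn and Adgrl3 were 2.41 and 1.41 (both reversed) in fibroblast-like cells. With the top 4% of doublet scores removed, Cdkn1a in fibroblast-like cells was 0.789.

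Share ratios of cells with a UMI were 1.12 for Cdkn1a over all cells thinned to 1000 UMIs, 0.753 for Cdkn1a in fibroblast-like cells at 2 or more UMIs, and, without thinning, 0.627 for Cdkn2a over all and 0.569 in fibroblast-like cells. Thinned to 1000 UMIs, the SASP ratios in the young and aged library were 1.02 (reversed) and 0.959 in fibroblast-like, 1.02 and 1.21 in macrophage/monocyte-like and 1.03 and 0.868 in neutrophil-like cells, 1.12 and 0.937 in cluster 4 and 0.962 and 0.874 in cluster 16. With at least 200 UMIs, 13 rather than 20 genes met the size rule in cluster 16.

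With TMM scaling the median of the senescence core was -0.18 over all, -0.20 in fibroblast-like and -0.12 (reversed) in macrophage/monocyte-like cells and -0.0729 (reversed) in cluster 4. SASP chemokines were 0.0248 over all, 0.0415 in fibroblast-like, -1.06 in macrophage/monocyte-like and -0.48 in neutrophil-like cells, and SASP cytokines -0.0563 over all cells. Over all cells collagen (-0.0107), contractile (-0.0586), hypoxia (-0.0163) and antioxidant (-0.0269) medians reversed, and in macrophage/monocyte-like cells SASP growth factor (-0.0364), p53 target (-0.10), efferocytosis (-0.10), antioxidant (-0.18) and dissociation stress (-0.25) medians. Proliferation in fibroblast-like cells was 0.38, and macrophage/monocyte-like interferon, alternative and inflammatory medians were -0.64, 0.29 and -1.11.

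With 1 CPM added, the senescence core was -0.14 over all cells, proliferation 0.59 and interferon 1.26 in fibroblast-like cells, and SASP chemokines -0.79 in macrophage/monocyte-like cells. With 20 CPM, fibroblast-like medians were -0.0876 for the senescence core, 0.0905 for SASP chemokines, 0.24 for proliferation and 0.64 for interferon, macrophage/monocyte-like ones -0.26 for interferon and -0.81 for inflammatory genes, and neutrophil-like SASP chemokines -0.33. With no UMI minimum, SASP chemokines were 0.0677 in fibroblast-like and -0.49 in macrophage/monocyte-like cells, where the senescence core was 0.10, and angiogenesis reversed to -0.0291 in neutrophil-like cells and 0.10 in cluster 16. With at least 100 UMIs, angiogenesis in neutrophil-like cells was -0.16 and interferon in cluster 16 0.0516, both reversed. With the top 4% of doublet scores removed, the senescence core was -0.15 over all cells, SASP chemokines -0.75 and inflammatory genes -0.90 in macrophage/monocyte-like cells, SASP chemokines -0.21 in neutrophil-like cells, and collagen in macrophage/monocyte-like cells (-0.0215) and inflammatory genes in cluster 4 (0.00818) reversed.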

Other observations

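The values here were looked at after the main results were seen. MHC class II genes, which present antigen to helper T cells, were higher in aged fibroblast-like cells, with 5 of 7 members at a ratio of 1.5 or more, but few cells carried them. The 10 cells with the most UMIs held 78.5% of aged H2-Aa, 56.7% of H2-Ab1, 84.3% of H2-Eb1 and 76.1% of Cd74. Without these cells in each library the ratios were 2.48, 2.08, 1.89 and 1.77. In cluster 4, where the list median was 1.72, 10 aged cells held 97.1% of H2-Aa and 96.8% of Cd74 UMIs, and without such cells the ratios of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were 1.51, 0.986, 1.88 and 0.619. That list median in cluster 4 was 0.90 with 20 CPM added, 0.91 with no UMI minimum and 0.13 without the cells with the top 4% of doublet scores.

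At the finer clustering, lymphocytes parted into a cluster nearest the T cell markers, with 220 young and 5 aged cells, and one nearest the NK and innate lymphoid markers, with 132 and 50. A keratinocyte cluster held 114 and 73 cells at a median of 1377 UMIs, and an erythroid cluster 70 and 121. Cluster 23 expressed Acp5, the tartrate-resistant phosphatase of osteoclasts, Atp6v0d2, a proton pump subunit, and the gelatinase gene Mmp9, at a median of 35288 UMIs.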
